A study of Mus musculus with 9 samples.

How the data were processed

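Left ventricular tissue from 9 wild-type mice was profiled by bulk mRNA sequencing, per the labels. The labels place 3 biological replicates in each of 3 groups. ND AAV-CON mice received a control vector under the diet labelled ND, read here as normal diet. HFD AAV-CON mice received the control vector under the diet labelled HFD, read here as high-fat diet, and HFD AAV-BCKDK mice received a vector named for the kinase BCKDK under the same diet. AAV stands for adeno-associated virus. Diet composition, duration, vector dose and promoter are not given in the sources used here. RNA was isolated with Trizol and made into libraries with the VAHTS mRNA-seq v2 kit, per the labels' protocols. HISAT2 version 2.0.5 and the mouse build mm10 were named per the submitters' processing notes. The counting tool, its annotation and whether strand was used are not given in the sources used here.

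The deposited values are raw read counts per gene, 1 value per library, with no normalization by the authors. The table held 26178 entries, of which 22036 carried Ensembl gene identifiers and 4142 were loci without a gene name. The unnamed loci held between 1.02% and 6.02% of the counts of a library and were left out of library sizes and tests. Of the annotated genes, 4856 had no read in any library. Counts in annotated genes ranged from 32803233 to 45483044 per library. The counts of replicates within a group differed by more than sampling noise in all 9 pairs, with a chi-square per degree of freedom of at least 10.6, so no library differed from another by read sampling alone. Each library was counted as 1 replicate, as labelled. These values do not test whether HFD AAV-CON replicate 3 was independent, since a pool of other libraries would also exceed sampling noise.

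Counts of annotated genes were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 14160, and libraries were scaled with TMM factors. A quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all 9 libraries, which then shared 1 estimate of the spread, and P values were adjusted with the Benjamini-Hochberg method at a false discovery rate of 0.05. Every adjusted p of a gene given in the text comes from this edgeR quasi-likelihood test unless another tool is named. Fold changes are on the log2 scale, and the standard error (SE) of a fold change was taken from the F statistic of its test. CPM, the usual depth-scaled count, was computed here from the deposited counts and TMM-scaled library sizes, and the spread of CPM is the standard deviation (SD) over 3 replicates. The common biological coefficient of variation was 18.6%.

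Tests were made for HFD AAV-CON against ND AAV-CON, for HFD AAV-BCKDK against HFD AAV-CON, and for HFD AAV-BCKDK against ND AAV-CON. In the last of these, diet and vector differ together. Genes called in both of the first comparisons with opposite signs are described as moved back. Because these comparisons share the HFD AAV-CON libraries, their correlation and covariance were set beside 1000 simulations of unchanged groups. Bckdk was also tested with an exact two-sided permutation test.

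Gene lists, 45 in number, covered metabolism, contraction, matrix, stress, immune and signalling pathways, markers of cell types that heart tissue could hold, and signs of RNA quality. Each was tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01 and adjusted over all lists within a comparison. Members that passed are counted over all genes tested and, where stated, adjusted over the list alone. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, served as alternatives.

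The design, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named Bckdk, the 10 genes that rose and the 10 that fell most in each comparison among those called, with an average log2 CPM of at least 1 and groups that did not overlap, leaving out predicted-gene symbols. It also named up to 4 members with the smallest p of each list described and 10 genes moved back with the smallest p in both comparisons. Some genes that the rule names are not reported here. Genes given outside this rule are said to have been chosen after their values were seen. Alternatives were RLE and upper-quartile factors, other filters on low counts, DESeq2 1.42.0, limma-voom, robust dispersion, a replicate block, fits of 2 groups alone, other thresholds, and leaving out each library. Alternatives added after seeing the data were total-count scaling, keeping unnamed loci, leaving out mitochondrial genes, voom with group weights, offsets for GC content and length, and thinning to equal totals or to equal TMM-scaled sizes.

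The pipeline was tested on simulated data built from the diet comparison over 14160 genes with 200 changed genes in 3 runs. It recovered 73% of genes changed 2-fold and 96.7% of genes changed 4-fold. False calls made up 3.6% of calls, and 0 calls had the wrong sign. The simulation gave changed genes random signs and all groups the same spread. In the real data 6134 genes were called with diet, and HFD AAV-CON libraries varied more than ND AAV-CON libraries (median SD 0.203 against 0.141). These rates therefore need not hold for the calls reported below. Gene positions and overlaps were taken from the GENCODE M21 annotation of mm10. Among genes named below, Acadsb, Adam1a, Aldh6a1, Arhgap20, Atf3, Atf5, Ccl2, Ccna2, Ciita, Cngb3, Col1a2, Col3a1, Col4a1, Dbp, Dbt, Dusp8, Ehhadh, Eomes, Fn1, G6pdx, Gabarapl1, Gadd45a, Gclm, Gpr22, Gzmk, Hibch, Idi1, Il18bp, Irf7, Irs2, Junb, Ltbp2, Manf, Map3k20, Mapk4, Mapkapk5, Mki67, Mthfd2, Myoz2, Ncf1, Ndufb5, Ndufs1, Nppa, Nr1d1, Oas2, Pax5, Pcx, Pln, Ppm1k, Rasl10a, Rbm3, Rcan1, Rps6ka5, Rtp4, Scgb1c1, Scml4, Slfn2, Slpi, Sucla2, Tap2, Tbc1d16, Thbs1, Timp1, Tnc, Tnfaip2, Tnfrsf19, Top2a, Trdn, Ucp2, Ucp3 and Xirp1 overlap another annotated gene. Positions of Nuak1 and P4ha2 were not looked up. Without known strand, reads in such overlaps cannot be told apart. The haemoglobin, histocompatibility and Hspa1 genes have near-identical copies. The values of all these genes are therefore uncertain to that extent. Where a group had 0 counts, a bound on the fold was computed from a floor of 3 counts over the group, and an interval of 95% was exact binomial. Floors and intervals cover counting error only.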

Results

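Left ventricular transcriptomes were compared between mice under normal diet with a control vector (ND AAV-CON), mice under high-fat diet with the control vector (HFD AAV-CON) and mice under high-fat diet with the BCKDK vector (HFD AAV-BCKDK), with 3 biological replicates per group. The series asks whether BCKDK, the mitochondrial kinase that phosphorylates and inhibits branched-chain α-ketoacid dehydrogenase, modifies cardiac remodelling in obesity through mitochondrial reactive oxygen species and the JNK and p38 kinases. Annotated genes received 40282399, 40419470 and 41430581 counts in the ND AAV-CON libraries. The HFD AAV-CON libraries held 43993009, 36216346 and 34265273, and the HFD AAV-BCKDK libraries 33150939, 32803233 and 45483044. Mitochondrially encoded transcripts took 45.7%, 43.4% and 42.1% of annotated counts in ND AAV-CON, 26.1%, 39.9% and 33.2% in HFD AAV-CON, and 45.3%, 47.6% and 45.0% in HFD AAV-BCKDK. The first principal component carried 62.2% of the variance and separated HFD AAV-CON from the other 6 libraries. The median SD of log2 CPM within a group was 0.14 in ND AAV-CON, 0.20 in HFD AAV-CON and 0.15 in HFD AAV-BCKDK.

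Bckdk (ENSMUSG00000030802), on mm10 chromosome 7 from 127904082 to 127910221 on the plus strand, was highest in the group that received the BCKDK vector. Its level was 73.2 ± 4.69 CPM (SD, n = 3) in ND AAV-CON, 50.5 ± 14.0 CPM in HFD AAV-CON and 119 ± 7.5 CPM in HFD AAV-BCKDK. It rose by 1.24 on the log2 scale (SE 0.17, adjusted p = 0.0016) between HFD AAV-CON and HFD AAV-BCKDK, and no library of one group overlapped the other. Under the diet it fell by 0.54 (SE 0.17, adjusted p = 0.030). Against ND AAV-CON the HFD AAV-BCKDK group differed by 0.70 (SE 0.17, adjusted p = 0.070). The exact permutation p was 0.1 in each comparison, the smallest that 3 against 3 can give. It treats the libraries as independent, which is not settled for HFD AAV-CON replicate 3. The call for the diet was lost without ND AAV-CON replicate 1 (adjusted p = 0.0905), 2 (0.0616) or 3 (0.0553), without HFD AAV-CON replicate 1 (0.0525) or 3 (0.0852), and with total-count scaling, where the diet value was -0.18 and the vector value 0.82.

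**Figure D1:**
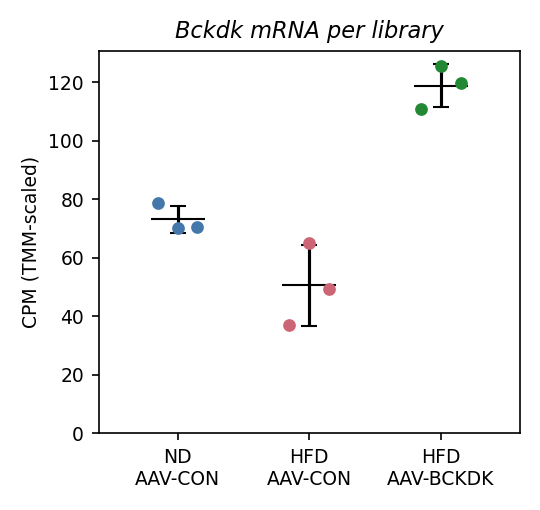
Bckdk mRNA in CPM (TMM-scaled, vertical axis) for each group (horizontal axis). Points are libraries, horizontal lines are means and bars are SD of 3 libraries. The means were 73.2, 50.5 and 119 CPM.

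The comparison of HFD AAV-CON with ND AAV-CON addressed the effect of the diet under the control vector. Genes of the extracellular matrix, interferon response, inflammation and cell division were higher in HFD AAV-CON hearts, and genes of oxidative phosphorylation, branched-chain amino acid (BCAA) breakdown, fatty acid oxidation and contraction were lower. Camera called each of these lists with the preset correlation and none with an estimated one (adjusted p = 0.477 for each). Falls were called for 56 of 58, 24 of 28, 13 of 25 and 17 of 25 members of the last 4, and rises for 41 of 46 matrix, 34 of 34 interferon, 26 of 36 inflammatory and 25 of 28 cell cycle genes. Sprr1a, a cornified-envelope protein induced in stressed cardiomyocytes, rose by 6.31 on the log2 scale (SE 0.91). The collagen-binding proteoglycan Fmod rose by 5.62 (SE 0.97), the matrix proteins Comp by 5.14 (SE 0.86) and Tnc by 5.02 (SE 0.62), and Ltbp2, which binds the matrix fibrillin network, by 4.36 (SE 0.61). Acod1, which makes itaconate in activated macrophages, rose by 4.80 (SE 0.77), C1qtnf3 by 4.50 (SE 0.996), Apol11b by 4.40 (SE 0.52), the stress cytokine Gdf15 by 4.40 (SE 0.53) and the antiviral synthetase Oas3 by 4.38 (SE 0.42). Fmod, Comp and C1qtnf3 varied widely within HFD AAV-CON, at 38.2 ± 32.05, 79.9 ± 66.8 and 6.66 ± 5.44 CPM (SD, n = 3). Acod1 and Apol11b varied less, at 5.16 ± 1.35 and 7.03 ± 1.21 CPM. Fmod held 4202, 145 and 1816 counts in HFD AAV-CON replicates 1, 2 and 3. The genes that fell most included Klhl33 (-3.18, SE 0.29), Cngb3 (-3.11, SE 0.23), the mitochondrial carrier Ucp3 (-3.06, SE 0.36), the peroxisomal fatty acid enzyme Ehhadh (-2.74, SE 0.27), Tnfrsf19 (-2.72, SE 0.35), AK157302 (-2.91, SE 0.29) and Inmt (-2.82, SE 0.53). Retnla fell by 2.93 (SE 0.88). The call of Retnla was lost without HFD AAV-CON replicate 3 (adjusted p = 0.0844) or ND AAV-CON replicate 1 (0.0645). Pcdhga2 fell by 2.50 (SE 0.46) but shares exons with the protocadherin gamma cluster and is uncertain.

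Matrix genes rose almost as a group. Of 46 members tested, 41 rose, 1 fell and 4 were not called, and 42 rose when adjusted over the list alone (camera adjusted p = 9.33e-14; adjusted p = 0.477 with an estimated correlation). The median change was 1.57. Thbs1, a matricellular regulator of TGF-β, rose by 3.79 (SE 0.21, adjusted p = 8.02e-05), the collagen chaperone Serpinh1 by 1.74 (SE 0.10), the collagen prolyl hydroxylase P4ha1 by 1.78 (SE 0.14) and the basement membrane collagen Col4a1 by 0.98 (SE 0.09). Fibroblast markers moved alongside, with 11 of 16 rising and 5 not called (adjusted p = 0.0027; adjusted p = 0.477 with an estimated correlation). Among them Col1a1 rose by 2.28 (SE 0.27), Col1a2 by 2.11 (SE 0.29) and Col3a1 by 2.29 (SE 0.33). Cell cycle genes also rose, 25 of 28 with 3 not called (adjusted p = 1.74e-10; adjusted p = 0.477 with an estimated correlation), including the kinase Cdk1 by 1.59 (SE 0.14), Ccna2 by 1.46 (SE 0.14), Mki67 by 1.77 (SE 0.17) and Top2a by 1.97 (SE 0.21). Cardiac stress genes rose in 11 of 21 cases, with 1 fall and 9 not called (adjusted p = 0.0011; adjusted p = 0.477 with an estimated correlation). Of these, the actin cross-linker Flnc rose by 1.22 (SE 0.11), Rcan1, a calcineurin target, by 1.61 (SE 0.17) and the intercalated disc gene Xirp1 by 1.35 (SE 0.15).

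Interferon, antigen presentation and inflammatory genes rose, as did most macrophage and T and NK cell markers. All 34 interferon response genes rose (median 1.57, adjusted p = 7.14e-15; adjusted p = 0.477 with an estimated correlation), among them Ifit1 by 1.73 (SE 0.13), Isg15 by 1.89 (SE 0.17) and Bst2 by 1.62 (SE 0.15). All 18 antigen presentation genes rose as well (median 2.19, adjusted p = 2.04e-08; adjusted p = 0.477 with an estimated correlation), including the peptide transporter Tap2 by 1.37 (SE 0.18) and the class I gene H2-D1 by 1.79 (SE 0.24). Inflammatory cytokines and chemokines gave 26 rises, 1 fall and 9 members not called of 36 (adjusted p = 9.13e-08; adjusted p = 0.477 with an estimated correlation), with the monocyte chemokines Ccl2 up by 2.21 (SE 0.22) and Ccl7 by 2.84 (SE 0.34) and the prostaglandin synthase Ptgs2 by 3.06 (SE 0.33). Macrophage and monocyte markers rose in 19 of 21 cases (median 1.80, adjusted p = 1.91e-08; adjusted p = 0.477 with an estimated correlation), with C1qa up by 1.80 (SE 0.22) and Cd14 by 2.05 (SE 0.22). T and NK cell markers rose in 10 of 14 cases (median 2.91, adjusted p = 0.0011; adjusted p = 0.484 with an estimated correlation), with Il7r up by 2.79 (SE 0.55) and Cd4 by 2.37 (SE 0.54). Neutrophil markers rose in 3 of 9 cases (adjusted p = 0.0267; adjusted p = 0.477 with an estimated correlation and 0.122 with total-count scaling), among them Csf3r by 2.58 (SE 0.29). Of the list of oxidant producers, 8 of 12 rose (adjusted p = 0.0099; adjusted p = 0.477 with an estimated correlation and 0.0752 with total-count scaling), led by the phagocyte NADPH oxidase subunits Ncf1 at 2.06 (SE 0.23), Cybb at 2.35 (SE 0.33) and Ncf4 at 2.52 (SE 0.39).

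Energy metabolism genes fell. Of 58 nuclear-encoded oxidative phosphorylation genes, 56 fell and 2 were not called (median -0.78, adjusted p = 3.96e-12; adjusted p = 0.477 with an estimated correlation). The complex I subunits Ndufa12 (-1.21, SE 0.21), Ndufs8 (-0.83, SE 0.19) and Ndufb5 (-0.88, SE 0.20) were among them. All 20 genes of the tricarboxylic acid cycle list fell (adjusted p = 9.39e-07; adjusted p = 0.477 with an estimated correlation), including pyruvate carboxylase Pcx (-0.95, SE 0.12) and Sucla2 (-0.84, SE 0.19). BCAA catabolism gave 24 falls, 1 rise and 3 members not called of 28, with 25 falls when adjusted over the list alone (median -0.83, adjusted p = 2.39e-08; adjusted p = 0.477 with an estimated correlation). Within it Dbt, the E2 subunit of the dehydrogenase that BCKDK inhibits, fell by 1.35 (SE 0.14). So did Ppm1k, the phosphatase that opposes BCKDK (-1.63, SE 0.17), Acadsb (-0.91, SE 0.11) and Aldh6a1 (-1.31, SE 0.21). Fatty acid oxidation gave 13 falls and 12 members not called of 25, and 19 falls when adjusted over the list alone (adjusted p = 5.81e-06; adjusted p = 0.477 with an estimated correlation), with the carnitine transporter Slc22a5 down -0.89 (SE 0.12) and Mlycd down -1.14 (SE 0.24). In the list of PPARα targets 13 of 24 fell and only Ucp2 rose, by 1.51 (SE 0.22), while Pdk4, which restrains glucose oxidation, fell by 1.79 (SE 0.24) (adjusted p = 3.21e-04; adjusted p = 0.477 with an estimated correlation). Mitochondrially encoded mRNAs fell in 5 of 13 cases, or 9 when adjusted over the list alone (adjusted p = 2.28e-04; adjusted p = 0.477 with an estimated correlation). Their share of counts was 26.1% to 39.9% in HFD AAV-CON against 42.1% to 45.7% in ND AAV-CON.

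Genes of the working cardiomyocyte fell with them. Contractile and calcium-handling genes gave 17 falls and 8 members not called of 25 (adjusted p = 2.61e-06; adjusted p = 0.477 with an estimated correlation), including Trdn, which anchors the calcium release complex (-0.78, SE 0.14), the calcium pump inhibitor Pln (-0.97, SE 0.21) and the Z-disc gene Myoz2 (-0.67, SE 0.13). Ion channel genes fell in 11 of 21 cases (adjusted p = 0.0011; adjusted p = 0.477 with an estimated correlation), among them Kcnip2, a subunit of the transient outward potassium channel (-1.54, SE 0.27). Cardiomyocyte markers fell in 11 of 16 cases, with 4 not called (adjusted p = 2.75e-04; adjusted p = 0.477 with an estimated correlation). The exception was Nppa, the atrial natriuretic peptide gene, which rose by 2.51 (SE 0.61). Endothelial markers fell in 8 of 16 cases (adjusted p = 0.0011; adjusted p = 0.477 with an estimated correlation), including Emcn (-0.94, SE 0.10) and the VEGF receptor Kdr (-0.72, SE 0.14). Their median was -0.436, or -0.0796 with total-count scaling. All 8 erythroid markers fell (adjusted p = 3.88e-04; adjusted p = 0.477 with an estimated correlation), with Hbb-bs down -1.31 (SE 0.23). Genes of mitochondrial dynamics and mitophagy fell in 20 of 27 cases (adjusted p = 1.86e-05; adjusted p = 0.477 with an estimated correlation), led by Gabarapl1 at -0.95 (SE 0.13). Glycolysis and glucose oxidation genes gave 15 falls and 5 rises of 31 (adjusted p = 0.0035; adjusted p = 0.484 with an estimated correlation), with Pdp1 down -0.96 (SE 0.11) and the glycolytic Pgam1 up 1.06 (SE 0.09).

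Stress responses and signalling genes were mixed. Of 29 genes of the unfolded protein and integrated stress responses, 22 rose, 3 fell and 4 were not called (adjusted p = 1.43e-08; adjusted p = 0.477 with an estimated correlation), including the endoplasmic reticulum genes Manf by 1.70 (SE 0.11), Sdf2l1 by 2.50 (SE 0.17) and Creld2 by 1.99 (SE 0.14). Heat shock genes rose in 12 of 16 cases (adjusted p = 1.79e-04; adjusted p = 0.477 with an estimated correlation), with the chaperones Hsp90aa1 up 1.495 (SE 0.15) and Hsph1 up 1.44 (SE 0.18). Immediate early and AP-1 genes rose in 14 of 28 cases (adjusted p = 3.39e-05; adjusted p = 0.477 with an estimated correlation), with Egr2 up 3.58 (SE 0.42) and Junb up 1.30 (SE 0.17). Apoptosis genes gave 17 rises and 2 falls of 28 (adjusted p = 3.70e-04; adjusted p = 0.477 with an estimated correlation), led by the TWEAK receptor Tnfrsf12a at 1.86 (SE 0.12). The list of JNK and p38 pathway components, the kinases named in the series question, was not called by camera (adjusted p = 0.186) and held 6 rises, 12 falls and 16 members not called. The fry test called it downward (adjusted p = 0.0139), and its median of -0.09 was 0.31 with total-count scaling. Its members with the smallest p all fell, namely the stress-induced Gadd45a (-1.74, SE 0.18), the p38 activator Map2k6 (-1.42, SE 0.24), the oxidant-responsive kinase Map3k5 (-0.54, SE 0.09) and Rps6ka5 (-0.87, SE 0.14). Antioxidant and NRF2 target genes were not called as a list either (adjusted p = 0.289), with 11 rises and 16 falls of 36. These are mRNA levels, and phosphorylation of JNK or p38 was not measured here. Insulin, mTOR and AMPK signalling genes were called (3 rises, 11 falls of 30, median -0.18, adjusted p = 0.0081; adjusted p = 0.477 with an estimated correlation), but their median was 0.20 with total-count scaling, where the call was lost (adjusted p = 0.122). Cytosolic ribosomal protein genes, with 1 rise and 6 falls of 46, had a median of -0.17 (adjusted p = 0.0014; adjusted p = 0.576 with an estimated correlation) that reversed to 0.22 with total-count scaling (adjusted p = 0.756). The fry test did not call them (adjusted p = 0.0879).

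In edgeR, genes changed by high-fat diet numbered 6134 (43.3%) of 14160 tested, 3215 up and 2919 down. Of these, 1481 rose and 505 fell by at least 2-fold. Groups did not overlap for 55.3% of all genes, where chance gives 10% for independent libraries. That independence is not settled for HFD AAV-CON replicate 3. With total-count scaling 6920 were called, 5986 up and 934 down, as the median of all genes then lay at 0.40, so directions hold relative to the typical gene. Without HFD AAV-CON replicate 3, whose counts lay between those of the other 2 libraries of its group, 4050 were called, 2326 up and 1724 down. Of 45 lists 30 were called, 15 in each direction, 0 with an estimated correlation in camera (2 at an unadjusted p under 0.05) and 33 with fry. The 15 lists that camera did not call included markers of pericytes and smooth muscle (adjusted p = 0.110), B and plasma cells (0.0572), adipocytes (0.091), atrial tissue (0.808), mesothelium (0.482), Schwann cells and neurons (0.925), skeletal muscle (0.333) and liver and serum proteins (0.837). Circadian clock (0.346), glucocorticoid-responsive (0.482), cholesterol synthesis (0.808), lipid synthesis (0.290) and sex-linked (0.148) genes were not called either. Of these, fry called B and plasma cell markers upward (adjusted p = 0.0401) and skeletal muscle markers (0.0406) and sex-linked genes (0.0420) downward. With total-count scaling camera called adipocyte (adjusted p = 0.0109) and skeletal muscle (0.0265) markers downward.

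**Figure D2:**
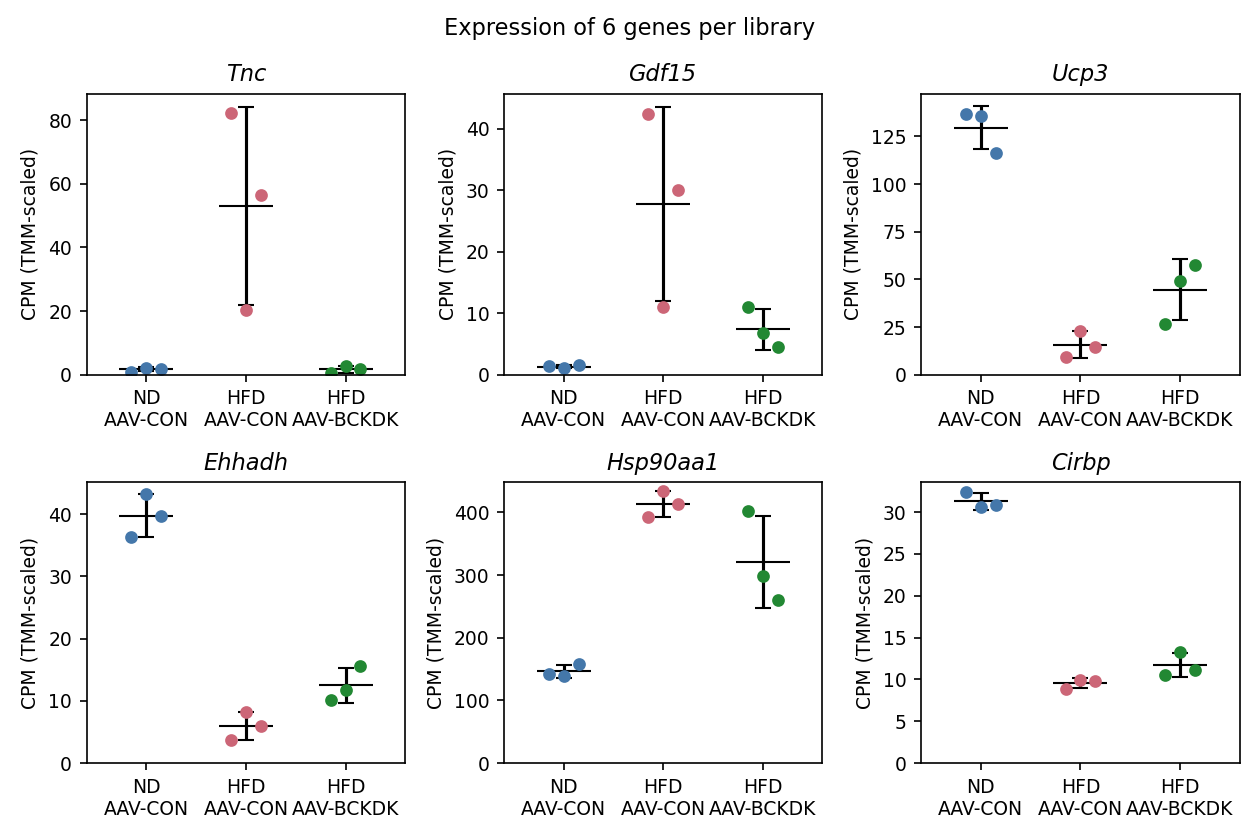
CPM (TMM-scaled, vertical axes) of Tnc, Gdf15, Ucp3, Ehhadh, Hsp90aa1 and Cirbp in each group (horizontal axes), with libraries as points, means as horizontal lines and SD of 3 libraries as bars. Tnc averaged 1.64 CPM in ND AAV-CON, 53.0 CPM in HFD AAV-CON and 1.76 CPM in HFD AAV-BCKDK, while Cirbp averaged 31.3, 9.55 and 11.7 CPM.

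The comparison of HFD AAV-BCKDK with HFD AAV-CON addressed the effect of the BCKDK vector under the high-fat diet. Interferon (31 of 34 called), antigen presentation (18 of 18), inflammatory (25 of 36), matrix (42 of 46) and cell cycle (25 of 28) genes were lower in the BCKDK group. Genes of oxidative phosphorylation (54 of 58), fatty acid oxidation (24 of 25) and contraction (17 of 25) were higher. Camera called each of these lists with the preset correlation and none with an estimated one (adjusted p = 0.399 for each), and it did not call neutrophil markers (adjusted p = 0.727). The protease inhibitor Slpi fell by 7.90 on the log2 scale (SE 1.40). Its counts in HFD AAV-CON were 4808, 428 and 2240. Others that fell most were Jchain, which joins immunoglobulin chains (-6.53, SE 1.58), the lymphocyte protease Gzmk (-6.03, SE 1.08), Fmod (-5.55, SE 0.98), the inhibitory T cell receptor Tigit (-5.41, SE 1.04), Coch (-5.07, SE 0.77), C1qtnf3 (-5.07, SE 1.06), Gbp2b (-5.03, SE 1.07) and Tnc (-4.92, SE 0.62). The T-box factor Eomes held 796 counts in HFD AAV-CON and 2 in HFD AAV-BCKDK, a ratio of 281 (95% counting interval 77.4 to 2320). Jchain varied widely in both control-vector groups, with 983, 24 and 7394 counts in ND AAV-CON and 14012, 2654 and 7349 in HFD AAV-CON. In HFD AAV-BCKDK its counts were 14, 41 and 124. The call of Jchain was lost without HFD AAV-BCKDK replicate 1 (adjusted p = 0.0510) or 2 (0.0506). Among genes that rose most, the clock output gene Dbp rose by 2.53 (SE 0.30), Gpr22 by 1.66 (SE 0.37), Rasl10a by 1.58 (SE 0.34), Arhgap20 by 1.55 (SE 0.24), Ucp3 by 1.52 (SE 0.34), Klra9 by 1.52 (SE 0.22), Adam1a by 1.51 (SE 0.33) and Mrgprh by 1.497 (SE 0.36). Chrna2 rose by 1.73 (SE 0.45), a call lost without HFD AAV-CON replicate 3 (adjusted p = 0.0631). Tbc1d16 was called at 2.11 (SE 0.68) but its counts in HFD AAV-CON were 199, 130 and 1125. That call was lost without ND AAV-CON replicate 1 (adjusted p = 0.0547) or 2 (0.0508), HFD AAV-CON replicate 1 (0.0660) and HFD AAV-BCKDK replicate 1 (0.0729), 2 (0.0828) or 3 (0.0716).

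Interferon genes fell in 31 of 34 cases (median -1.30, adjusted p = 5.27e-14; adjusted p = 0.399 with an estimated correlation), with Ifit1 down -1.82 (SE 0.13), Rtp4 down -0.997 (SE 0.11) and the interferon regulator Irf7 down -1.50 (SE 0.17). All 18 antigen presentation genes fell (median -2.31, adjusted p = 1.05e-09; adjusted p = 0.399 with an estimated correlation), led by the class II transactivator Ciita at -4.35 (SE 0.54). Inflammatory genes gave 25 falls and 1 rise of 36 (median -1.54, adjusted p = 1.19e-06; adjusted p = 0.399 with an estimated correlation), including Ptgs2 (-2.76, SE 0.33) and the T cell chemokine Cxcl9 (-3.81, SE 0.52). Il6 had 143 counts in HFD AAV-CON and 0 in all HFD AAV-BCKDK libraries, which makes it at least 33.6-fold lower. The list median was the same with Il6 at that bound. Macrophage markers fell in 20 of 21 cases and 1 rose (median -2.01, adjusted p = 5.67e-10; adjusted p = 0.399 with an estimated correlation), with C1qc down -1.997 (SE 0.20) and Lyz2 down -2.01 (SE 0.21). T and NK cell markers fell in 12 of 14 cases (median -3.90, adjusted p = 6.22e-05; adjusted p = 0.399 with an estimated correlation), with Il7r down -3.48 (SE 0.59). B and plasma cell markers fell in 7 of 11 cases (adjusted p = 0.0018; adjusted p = 0.399 with an estimated correlation and 0.0567 with total-count scaling), with Cd79a down -4.79 (SE 0.96). Their median was -3.86, or -3.39 with Pax5, which had 0 counts in the BCKDK group, at its bound. Oxidant producers fell in 7 of 12 cases and 1 rose (adjusted p = 0.0138; adjusted p = 0.399 with an estimated correlation and 0.106 with total-count scaling), with Cybb down -2.95 (SE 0.34) and Ncf1 down -2.26 (SE 0.23).

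Matrix genes fell in 42 of 46 cases with 4 not called (median -1.33, adjusted p = 9.17e-13; adjusted p = 0.399 with an estimated correlation), including Thbs1 (-2.74, SE 0.20), the protease inhibitor Timp1 (-3.34, SE 0.43) and fibronectin Fn1 (-2.20, SE 0.30). Fibroblast markers fell in 12 of 16 cases and 1 rose (adjusted p = 0.0051; adjusted p = 0.399 with an estimated correlation), with Col1a1 down -1.93 (SE 0.27). Cell cycle genes fell in 25 of 28 cases (adjusted p = 8.41e-11; adjusted p = 0.399 with an estimated correlation), with Mki67 down -1.83 (SE 0.17). Cardiac stress genes gave 8 falls and 1 rise of 21 (adjusted p = 0.0496; adjusted p = 0.532 with an estimated correlation), among them Nppa (-3.12, SE 0.63) and the stretch-responsive Ankrd1 (-1.39, SE 0.33). That list call was lost with total-count scaling (adjusted p = 0.106), with fry (0.0570) and without most single libraries. Unfolded protein and integrated stress genes gave 18 falls and 3 rises of 29 (adjusted p = 2.38e-04; adjusted p = 0.399 with an estimated correlation), and Sdf2l1 fell by 1.35 (SE 0.16). AP-1 genes fell in 19 of 28 cases (adjusted p = 5.31e-06; adjusted p = 0.399 with an estimated correlation), including Atf3 (-1.53, SE 0.21), and apoptosis genes in 20 of 28 with 2 rises (adjusted p = 2.27e-04; adjusted p = 0.399 with an estimated correlation). The heat shock list was not called (adjusted p = 0.529), with 2 rises, 2 falls and 12 members not called.

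Oxidative phosphorylation genes rose in 54 of 58 cases and 58 when adjusted over the list alone (median 0.75, adjusted p = 5.27e-14; adjusted p = 0.399 with an estimated correlation), including Ndufs1 by 0.73 (SE 0.18) and Ndufa12 by 0.88 (SE 0.21). All 20 tricarboxylic acid cycle genes rose (adjusted p = 1.69e-07; adjusted p = 0.399 with an estimated correlation). Fatty acid oxidation genes rose in 24 of 25 cases (median 0.88, adjusted p = 6.23e-08; adjusted p = 0.399 with an estimated correlation), with Slc22a5 up 0.70 (SE 0.12), while Cpt1a, the liver-type carnitine palmitoyltransferase, fell by 0.48 (SE 0.09). BCAA catabolism genes gave 24 rises, 1 fall and 3 members not called of 28 (median 0.69, adjusted p = 1.17e-07; adjusted p = 0.399 with an estimated correlation), among them Dbt by 0.79 (SE 0.14), Acadsb by 0.63 (SE 0.11), Acad8 by 0.52 (SE 0.11) and Hibch by 0.55 (SE 0.11). PPARα targets gave 14 rises and 2 falls of 24 (adjusted p = 1.48e-04; adjusted p = 0.412 with an estimated correlation), with the fatty acid transporter Cd36 up 0.80 (SE 0.18) and Ucp2 down -1.56 (SE 0.22). Mitochondrially encoded mRNAs rose in 11 of 13 cases (median 0.91, adjusted p = 3.41e-06; adjusted p = 0.399 with an estimated correlation), at 45.0% to 47.6% of counts. Contractile genes rose in 17 of 25 cases (adjusted p = 6.56e-08; adjusted p = 0.399 with an estimated correlation), with Trdn up 0.78 (SE 0.14). Cardiomyocyte markers rose in 9 of 16 cases and 1, Nppa, fell (adjusted p = 1.31e-04; adjusted p = 0.412 with an estimated correlation). Endothelial markers rose in 9 of 16 cases (adjusted p = 6.22e-05; adjusted p = 0.399 with an estimated correlation), with Kdr up 0.998 (SE 0.14), and all 8 erythroid markers rose (adjusted p = 5.73e-04; adjusted p = 0.399 with an estimated correlation). Ion channel genes rose in 8 of 21 cases (adjusted p = 0.0015; adjusted p = 0.435 with an estimated correlation). With total-count scaling the medians of the endothelial, ion channel and contractile lists were 0.038, 0.074 and 0.115, against 0.463, 0.497 and 0.548 with TMM. Oxidative phosphorylation genes had 0.344. These rises therefore hold relative to the typical gene.

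JNK and p38 pathway components were called upward at the margin, with 11 rises, 3 falls and 20 members not called of 34 (median 0.13, adjusted p = 0.0496; adjusted p = 0.399 with an estimated correlation), and by fry (adjusted p = 0.0179). The median was -0.32 with total-count scaling (adjusted p = 0.732), so its direction depends on the scaling, and the camera call was lost when any 1 library was left out. Map3k20 rose by 0.57 (SE 0.11), Mapkapk5, a kinase downstream of p38, by 0.47 (SE 0.09) and Rps6ka5 by 0.57 (SE 0.14), whereas Gadd45b, which activates upstream kinases, fell by 0.81 (SE 0.19). Antioxidant and NRF2 target genes gave 17 rises and 8 falls of 36 (median 0.28, or -0.16 with total-count scaling; adjusted p = 0.0456; adjusted p = 0.550 with an estimated correlation). Camera also called that list with total-count scaling (adjusted p = 0.0073). Hmox1, the inducible haem oxygenase, fell by 1.34 (SE 0.10), as did Gpx1 (-0.96, SE 0.12) and G6pdx (-1.11, SE 0.18), whereas Gclm, a subunit of the glutathione-synthesising ligase, rose by 0.47 (SE 0.08). Circadian clock genes gave 10 rises and 3 falls of 19 (adjusted p = 0.0292; adjusted p = 0.412 with an estimated correlation), with the nuclear receptors Nr1d1 up 1.20 (SE 0.15) and Nr1d2 up 1.22 (SE 0.11). Insulin, mTOR and AMPK genes gave 12 rises and 2 falls of 30 (median 0.11, or -0.33 with total-count scaling; adjusted p = 0.0328; adjusted p = 0.399 with an estimated correlation and 0.474 with total-count scaling). Ribosomal protein genes had a median of 0.17 (adjusted p = 6.43e-04; adjusted p = 0.550 with an estimated correlation), reversed to -0.28 with total-count scaling (adjusted p = 0.752).

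In edgeR, genes changed by AAV-BCKDK on high-fat diet numbered 5410 (38.2%), 2444 up and 2966 down, and by at least 2-fold 203 rose and 1461 fell. Groups did not overlap for 51.2% of all genes, where chance gives 10% for independent libraries, which is not settled for HFD AAV-CON replicate 3. With total-count scaling 7265 were called, 398 up and 6867 down, with the median of all genes at -0.47. The count was 2847 (984 up and 1863 down) without HFD AAV-CON replicate 3, 3434 without HFD AAV-CON replicate 1, and 3194 or 3403 without HFD AAV-BCKDK replicate 1 or 2. Of 45 lists, 33 were called, 19 up and 14 down, 0 with an estimated correlation in camera (1 at an unadjusted p under 0.05) and 28 with fry. The fry test did not call the lists of PPARα targets (adjusted p = 0.0505), glycolysis (0.0755), cardiac stress (0.0570), ion channels (0.0642), antioxidant defence (0.244) and ribosomal proteins (0.116). Lists that camera did not call included pericyte (adjusted p = 0.0945), neutrophil (0.727), skeletal muscle (0.664), cholesterol synthesis (0.160) and glucocorticoid-responsive (0.979) genes. Of these, fry called cholesterol synthesis downward (adjusted p = 0.0017). The other 3 called lists were mitochondrial dynamics (adjusted p = 4.90e-06; adjusted p = 0.399 with an estimated correlation), glycolysis (adjusted p = 0.0015; adjusted p = 0.436 with an estimated correlation) and adipocyte markers (adjusted p = 0.011; adjusted p = 0.399 with an estimated correlation).

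**Figure D3:**
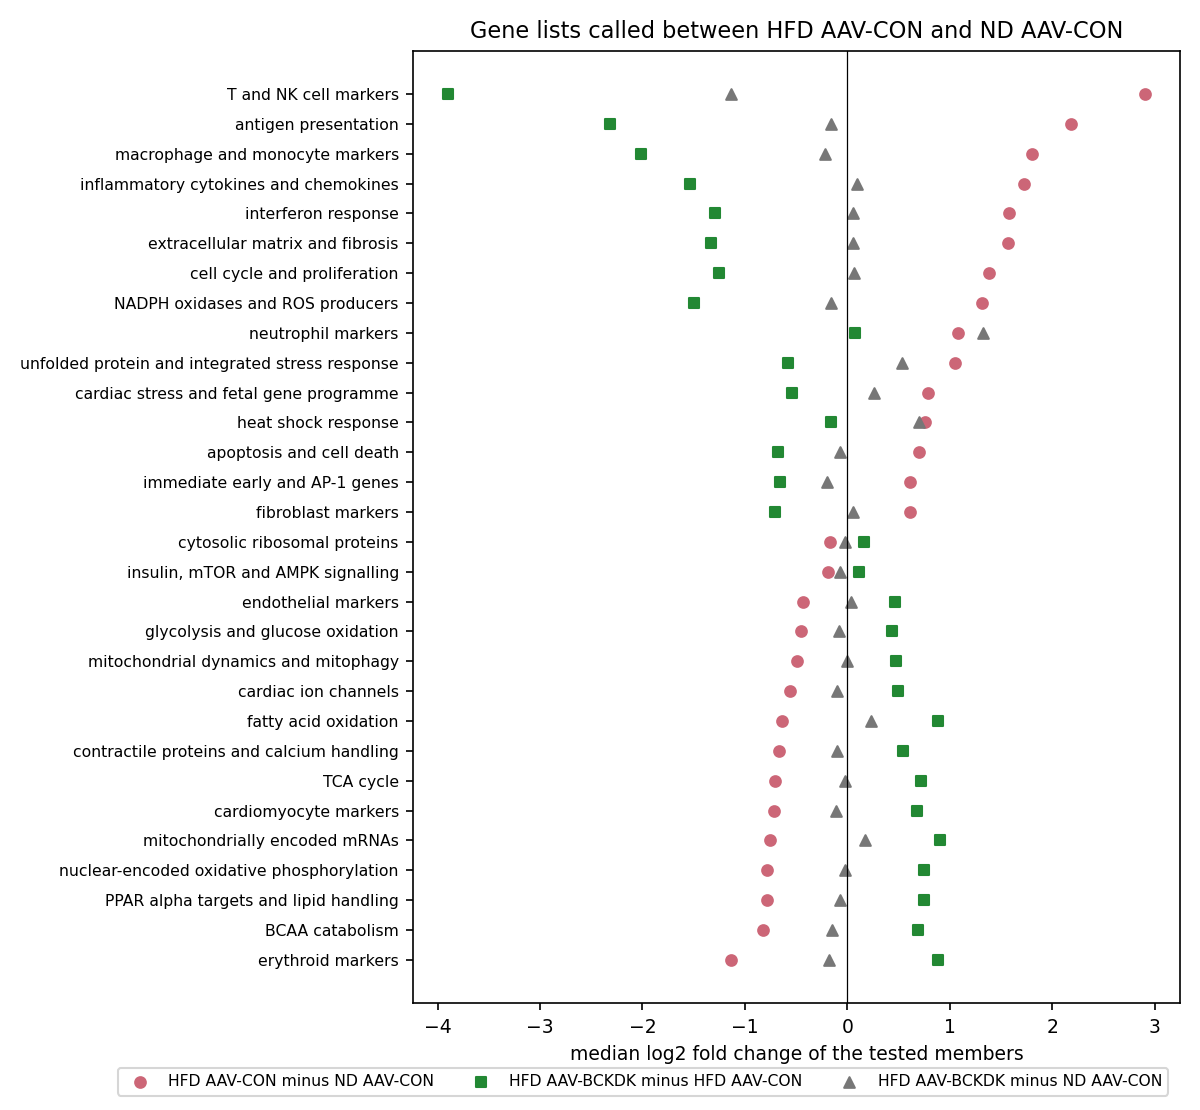
Median log2 fold change of the tested members (horizontal axis) of the 30 gene lists called between HFD AAV-CON and ND AAV-CON (vertical axis), for each of 3 comparisons, shown as circles, squares and triangles. The matrix list lay at 1.57, -1.33 and 0.06; medians are relative to TMM scaling, and with total-count scaling those of the ribosomal and insulin lists change sign in the circles and squares, that of the neutrophil list in the squares, and those of the interferon and endothelial lists in the triangles.

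Most genes changed by the diet were moved back in the BCKDK group. Thbs1 rose by 3.79 with diet, fell by 2.74 with the vector and remained 1.048 above ND AAV-CON (adjusted p = 0.0303). For Ifit1 the values were 1.73, -1.82 and -0.09, for the cytokine-binding Il18bp 1.68, -1.91 and -0.23, for Tnfaip2 1.27, -1.53 and -0.26, and for the actin-binding Tmsb10 1.20, -1.02 and 0.18. The protease inhibitor Cstb had 0.91, -1.07 and -0.16, the TNF receptor Tnfrsf1b 1.99, -2.04 and -0.05, Slfn2 1.81, -1.78 and 0.02, the proliferation marker Mki67 1.77, -1.83 and -0.05, and the lectin Clec4n 1.91, -1.85 and 0.06. Of the 6134 genes called with diet, 4220 (68.8%) were called in the opposite direction with the vector, 2414 up then down and 1806 down then up. Independent lists would share 673 and 504. Only 14 genes were called in both with the same sign, where independent lists would share 1166. The lists are not independent, since HFD AAV-CON enters the comparisons with opposite signs. That alone raises opposite-sign and lowers same-sign sharing. With total-count scaling 5512 were moved back, 5231 up then down and 281 down then up. The number of diet-changed genes moved back by AAV-BCKDK was 2215 (1559 and 656) without HFD AAV-CON replicate 3, 2616 without HFD AAV-CON replicate 1 and 2732 without HFD AAV-BCKDK replicate 1.

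Both comparisons use the HFD AAV-CON libraries, which favours a negative relation between them. Across genes, which are not independent replicates, the log2 fold changes correlated at -0.891, against a mean of -0.452 (range -0.992 to 0.254) in 1000 simulations without effects. The observed correlation lay within the simulated range. The fold changes were also compared by covariance and sign. Their covariance was -0.752, against a simulated mean of -0.0548, a difference of -0.697, and a simulated range of -0.439 to 0.0396. Signs were opposite for 84.1% of genes, against a mean of 70.6% in the simulations, whose range of 42.9% to 97.4% held the observed value. Splitting the controls would leave fewer than 2 libraries in a part, so no split was made. The simulations treat the HFD AAV-CON libraries as independent, which is not settled for replicate 3. Part of the excess may therefore still come from the shared libraries. When the 3 HFD AAV-CON libraries were kept as the middle group and the other 6 were divided in the 9 other ways, between 3719 and 3792 genes were moved back, against 4220 in the real division.

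The comparison of HFD AAV-BCKDK with ND AAV-CON addressed what still differed from normal diet with the vector present. In camera with the preset correlation the unfolded protein and integrated stress list (14 of 29 members called) and the heat shock list (6 of 16) were higher, and the cholesterol synthesis list (2 of 19) was lower. None was called with an estimated correlation (adjusted p = 0.217, 0.751 and 0.217), and fry did not call the heat shock list (adjusted p = 0.0911). Among the genes that rose most, the endothelin Edn3 rose by 2.84 on the log2 scale (SE 0.26), Tnfrsf12a (ENSMUSG00000023905, chromosome 17 from 23675445 to 23677468) by 1.91 (SE 0.12, adjusted p = 3.10e-04) and Nr1d1 by 1.80 (SE 0.15). Among those that fell most, Rasd1 fell by 2.54 (SE 0.28), the GABA transaminase Abat fell by 1.95 (SE 0.22) and Cngb3 fell by 1.69 (SE 0.21). These 6 calls held without any 1 library. Zfp235 rose by 2.67 (SE 0.54), Gdf15 by 2.48 (SE 0.52) and the actin-severing Scin fell by 1.57 (SE 0.34), but these calls were lost without each library other than HFD AAV-CON replicates 1 and 2, with adjusted p from 0.0661 to 0.148, 0.066 to 0.159 and 0.0548 to 0.158. Mapk4 rose by 1.497 (SE 0.30), D7Ertd443e fell by 2.26 (SE 0.40) and Scgb1c1 fell by 1.57 (SE 0.33). Their calls were lost without each ND AAV-CON library, HFD AAV-CON replicate 3 or HFD AAV-BCKDK replicate 2 or 3 (adjusted p from 0.065 to 0.128, 0.0505 to 0.109 and 0.0861 to 0.157). Scml4 rose by 1.47 (SE 0.30), lost without ND AAV-CON replicate 2 or 3, HFD AAV-CON replicate 3 or any HFD AAV-BCKDK library (adjusted p from 0.0822 to 0.144).

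Tnfrsf19 fell by 2.23 (SE 0.34), lost without ND AAV-CON replicate 1 or 2 or any HFD AAV-BCKDK library (adjusted p from 0.059 to 0.0707). Ehhadh fell by 1.67 (SE 0.26), lost without any ND AAV-CON library or HFD AAV-BCKDK replicate 1 or 2 (0.0522 to 0.0771). The BMP pseudoreceptor Bambi rose by 1.44 (SE 0.22), lost without any ND AAV-CON library or HFD AAV-BCKDK replicate 3 (0.0522 to 0.0725). Clec4d rose by 1.83 (SE 0.26), lost without ND AAV-CON replicate 1 or 2 (0.0584 and 0.0581). AK157302 fell by 2.07 (SE 0.28) and Klhl33 fell by 1.99 (SE 0.27), each lost without ND AAV-CON replicate 1 (0.0519 and 0.0542) or HFD AAV-BCKDK replicate 2 (0.0513 and 0.0531).

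The unfolded protein and integrated stress list gave 14 rises and 15 members not called of 29, with 20 rises and 1 fall when adjusted over the list alone (median 0.53, adjusted p = 4.80e-13; adjusted p = 0.217 with an estimated correlation). Atf5, a factor of the mitochondrial stress response, rose by 0.79 (SE 0.09), Manf by 0.87 (SE 0.11), the mitochondrial folate enzyme Mthfd2 by 1.40 (SE 0.19) and Sdf2l1 by 1.15 (SE 0.17). Heat shock genes rose in 6 of 16 cases and 9 when adjusted over the list alone (median 0.70, adjusted p = 1.70e-10; adjusted p = 0.751 with an estimated correlation), including Dnajb4 by 0.94 (SE 0.105) and Hsp90aa1 by 1.13 (SE 0.15). Cholesterol synthesis genes gave 2 falls and 17 members not called of 19 (median -0.27, adjusted p = 0.0042; adjusted p = 0.217 with an estimated correlation), with Idi1 down -1.14 (SE 0.21) and Mvk down -0.70 (SE 0.13). Cardiac stress genes rose in 4 of 21 cases (adjusted p = 0.0074; adjusted p = 0.995 with an estimated correlation), with Flnc up 0.95 (SE 0.11), Rcan1 up 1.02 (SE 0.17), Xirp1 up 0.70 (SE 0.15) and Gdf15. Matrix genes rose in 4 of 46 cases with a median of 0.06 (adjusted p = 0.0142; adjusted p = 0.995 with an estimated correlation), namely Serpinh1 by 1.32 (SE 0.10), P4ha1 by 1.24 (SE 0.14), Col4a1 by 0.53 (SE 0.09) and Thbs1 by 1.048 (SE 0.20). Interferon genes had 1 rise, Oas2 by 0.81 (SE 0.15), and 33 members not called (median 0.06, or -0.003 with total-count scaling; adjusted p = 0.0398; adjusted p = 0.995 with an estimated correlation). Neutrophil markers (median 1.32, adjusted p = 0.0042; adjusted p = 0.751 with an estimated correlation) and B and plasma cell markers (median -2.02, adjusted p = 0.0469; adjusted p = 0.995 with an estimated correlation and 0.0599 with total-count scaling) were called as lists with 0 of 9 and 0 of 11 members called in edgeR. At an unadjusted p under 0.05 these were 3 and 6, and DESeq2 called 1 and 2.

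Outside the called lists, Hmox1 fell by 1.54 (SE 0.10, adjusted p = 3.10e-04) while the antioxidant Srxn1 rose by 0.64 (SE 0.09), in a list that was not called (adjusted p = 0.560). Gadd45a fell by 1.33 (SE 0.18), Map2k6 fell by 1.34 (SE 0.24) and the JNK phosphatase Dusp8 rose by 0.80 (SE 0.15) in the JNK and p38 list (adjusted p = 0.876). Ppm1k fell by 0.81 (SE 0.17) in the BCAA list (adjusted p = 0.061), which was called downward with total-count scaling (median -0.21, adjusted p = 3.16e-04). Falls were also called for Pcx (-0.58, SE 0.12) in the tricarboxylic acid cycle list (adjusted p = 0.919), Ucp3 (-1.54, SE 0.34) among PPARα targets (adjusted p = 0.656) and Irs2, the insulin receptor substrate (-1.38, SE 0.30). Nr1d2 rose by 0.85 (SE 0.11) and Cry1 fell by 0.48 (SE 0.08) in the clock list (adjusted p = 0.0695). With total-count scaling the clock (adjusted p = 0.0154), fatty acid oxidation (0.0319) and mitochondrially encoded (0.0146) lists were also called, all upward.

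In edgeR, genes changed between HFD AAV-BCKDK and ND AAV-CON numbered 347 (2.45%), 167 up and 180 down, and 2405 had an unadjusted p under 0.05. Groups did not overlap for 27.7% of all genes, where chance gives 10%. Of the 347, 287 were also called with diet in the same direction and 2 in the opposite one. Both comparisons use the ND AAV-CON libraries, which favours the same direction, and no value for unchanged groups was computed. Total-count scaling gave 136, 51 up and 85 down, a replicate block 107, and DESeq2 gave 902. The count was 43, 64 or 87 without ND AAV-CON replicate 1, 2 or 3, 122 or 744 without HFD AAV-CON replicate 3 or 2, and 117, 73 or 87 without HFD AAV-BCKDK replicate 1, 2 or 3. Of 45 lists, 8 were called, 6 up and 2 down, 5 without HFD AAV-BCKDK replicate 2, 0 with an estimated correlation in camera (2 at an unadjusted p under 0.05) and 2 with fry, the unfolded protein and cholesterol synthesis lists. The matrix, cardiac stress, interferon and B and plasma cell calls were each lost without at least 1 library.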

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

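Both tests of HFD AAV-CON replicate 3 given here were chosen only after the results were seen.

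Reads in unnamed loci, which were left out of the comparisons except in an alternative that kept them, stood apart in HFD AAV-CON replicate 3. In that library 612 unnamed loci had reads that no other library had, against at most 211 for any other library. The most abundant unnamed locus averaged 2042798 reads over the other 8 libraries, from 1436357 to 2592903, and had 0 in HFD AAV-CON replicate 3. Among 204 unnamed loci with at least 100 reads in each of the other 8 libraries, 180 had fewer than 10 in this one, and 555 loci listed with the symbol 0 had 0 reads in any other library. These values argue against the unnamed loci of all 9 libraries having been defined and counted alike. Whether the annotated genes of this library were also processed apart was not tested.

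In annotated genes, HFD AAV-CON replicate 3 lay between replicates 1 and 2. A weighted sum of those libraries (weights 0.41 and 0.438) left a residual SD of 0.0854 on the log2 scale, against 0.118 to 0.269 for the same fit in the other 8 libraries. Of its genes 65.4% lay between both replicates, against 14.3% to 37.4% elsewhere. Pooled RNA or reads may be one explanation, but 13 of 8172 genes lay more than 2-fold outside both replicates (11 to 102 in the other libraries), such as Tbc1d16 at 1125 counts against 199 and 130, which argues against a plain sum of reads counted like the other libraries. An animal with an intermediate response may be the other, and its position between both replicates would then be expected to differ between lists. The SD of that position over 30 lists was 0.0522, against 0.141 for replicate 2 between ND AAV-CON and replicate 1. The smaller SD lies nearer to what pooling would give, but does not settle it. Pooling, with annotated genes also counted separately, and an intermediate animal cannot be told apart. The unnamed loci set the processing of this library apart under either explanation.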

How the results depend on the processing

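The alternatives with total-count scaling, voom group weights, unnamed loci kept, mitochondrial genes left out, GC and length offsets and thinning were chosen only after the data were seen. The number of genes changed between HFD AAV-BCKDK and ND AAV-CON was 347, but 902 with DESeq2, which shared all 347, 873 with 2 groups per fit, 831 with voom group weights, 685 at a false discovery rate of 0.1, 136 with total counts and 83 with at least a 2-fold change. Without single libraries they ranged from 43 to 744. With at least a 2-fold change, genes changed by high-fat diet numbered 1986, genes changed by AAV-BCKDK on high-fat diet 1664 and diet-changed genes moved back by AAV-BCKDK 1327, and with an unadjusted p and 2-fold change 2183, 1862 and 1478. Leaving out single libraries gave 4050 to 7325 genes for diet, 2847 to 6978 for the vector and 2215 to 5779 moved back. Bckdk under the vector stayed between 1.08 and 1.48 without single libraries. Estimated correlation left 0 lists called in the diet comparison, 0 in the vector comparison and 0 against ND AAV-CON. Lists called against ND AAV-CON numbered 8, but 5 with a filter at CPM 1 and 2 with fry, and 5 to 10 without single libraries. The ribosomal list reversed to 0.22 for diet and -0.28 for the vector with total counts. Stricter thresholds lower counts by construction. The HFD AAV-CON libraries are not part of the comparison against ND AAV-CON but share its estimate of the spread. Their median SD of log2 CPM was 0.203, against 0.141 in ND AAV-CON and 0.146 in HFD AAV-BCKDK. With 2 groups per fit, which leaves them out, the count was 873 in place of 347. Other causes were not tested.

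A replicate block changed the number of genes changed between HFD AAV-BCKDK and ND AAV-CON to 107 and moved no other count of genes by over 1.5 times. Replicate numbers did not pair the libraries: same-numbered libraries correlated between -0.22 and 0.192, 2 of 9 pairs over 0.1, and 0 libraries correlated best with their own number in both other groups. Of 63 named-gene results, 52 kept direction and call without HFD AAV-CON replicate 3, 47 without ND AAV-CON replicate 1 and 56 with total counts; 0 named genes reversed in any alternative.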

Other observations

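The tests of tissue stress, temperature and cell composition, both thinnings, the GC and length offsets, and the count with HFD AAV-CON kept as the middle group, were chosen only after the results were seen.

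In both HFD groups, 208 genes differed from ND AAV-CON in the same direction and were not called with the vector. Both comparisons use the same ND AAV-CON libraries, so noise in those libraries alone gives some agreement. No value for unchanged groups was computed. The 208 are among the 347 calls of the BCKDK group against ND AAV-CON, a number that fell without any 1 ND AAV-CON library. The genes named here were chosen after their values were seen. Cyp1a1, the aryl hydrocarbon receptor target on mm10 chromosome 9 from 57687928 to 57703824, had 142, 176 and 163 counts in ND AAV-CON and 0 in all 6 HFD libraries. It was at least 200-fold lower in HFD AAV-CON and at least 141-fold lower in HFD AAV-BCKDK. Whether the diets also differed in base, such as grain against purified, is not given in the sources used here, so this loss cannot be assigned to the fat content. Cirbp, a cold-inducible RNA-binding protein, fell by 1.71 (SE 0.10) with diet and by 1.42 (SE 0.10) against ND AAV-CON in the BCKDK group. The related Rbm3 fell by 0.75 (SE 0.11) and 1.35 (SE 0.11). Both were also called with the vector, at 0.29 for Cirbp and -0.60 for Rbm3. The collagen hydroxylase P4ha2 rose by 1.06 and 1.01, and the kinase Nuak1 by 1.16 and 1.17.

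Against ND AAV-CON, 12 of 16 heat shock genes were called higher in HFD AAV-CON and 6 of 16 in HFD AAV-BCKDK, and Cirbp was lower in both. These comparisons share the ND AAV-CON libraries. The list was called by camera in both, but not with an estimated correlation (adjusted p = 0.477 and 0.751), and fry did not call it in the BCKDK group (adjusted p = 0.0911). Tissue stress as in HFD AAV-CON stays open: in the BCKDK group against ND AAV-CON the heat shock median was 0.696 (bootstrap SD 0.177), with 0.059 for interferon and 0.0581 for matrix genes but 0.53 for unfolded protein and 0.261 for cardiac stress genes. A difference in tissue temperature before freezing may be another explanation, since 8 of 16 heat shock genes were higher in all 6 HFD libraries than in all 3 ND libraries, against 6.07% of all genes. Cirbp was lower in all 6 with either scaling, but Rbm3 only with TMM, as with total counts HFD AAV-CON replicate 1 lay at 70.8 against 65.5 to 69.4 in ND AAV-CON. Temperature and diet cannot be told apart because all HFD libraries share the diet.

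The diet calls and their return in the BCKDK group were set against technical explanations. A lower share of cardiomyocyte RNA would raise the markers of every other cell type alike, but the endothelial median was -0.436 (bootstrap SD 0.13) and the macrophage median 1.80 (bootstrap SD 0.171). With total-count scaling these medians were -0.0796 and 2.23. The fall of endothelial markers thus depends on the scaling, while the distance between both medians does not. Thinning left 6063 genes changed by high-fat diet at equal totals of annotated counts and 5896 at equal TMM-scaled sizes, and offsets for GC content and length left 6275, against 6134. The covariance of -0.752 lay below the lowest of 1000 simulations with shared controls, -0.439. Those simulations treat the HFD AAV-CON libraries as independent, which is not settled for replicate 3. They therefore do not exclude the shared libraries as the source. A change in cell types, such as immune infiltration, and a response to diet and vector stay open, and both may act together.

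In other splits of the 6 libraries of each pair, the count of the real split was the highest, 1 of 10 in each, too few splits for a share under 0.05. The real and highest other counts in edgeR were 6134 and 0 for diet, 5410 and 0 for the vector and 347 and 0 against ND AAV-CON. Every other split mixes libraries of both groups, so a group difference widens the spread and lowers its count. The counts of 0 therefore do not show what chance would give. At an unadjusted p under 0.05 the highest other splits gave 1451, 1799 and 629. The 9 libraries can be assigned to 3 groups in 840 distinct ways, of which 100 were tried, the real one among them. Only the real one gave as many moved-back genes, 4220 against 3719 in the highest other. That highest other kept the 3 HFD AAV-CON libraries together as the middle group, and the highest assignment without them together gave 26. The number moved back therefore rests mainly on HFD AAV-CON standing apart from the other 6 libraries. These assignments treat the 9 libraries as independent, which is not settled for HFD AAV-CON replicate 3, so chance is not excluded.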
